A study of Mus musculus with 8 samples.

How the data were processed

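Expression of messenger RNA was measured in 8 samples of cultured mouse chondrocytes, 4 untreated and 4 treated with TNF. Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a stranded poly(A) kit, and all 8 were pooled equally and run together on a NextSeq 500 with paired-end reads of 75 bp. The authors deposited 1 table of counts per sample, with an Ensembl gene identifier, a symbol and a whole-number count of reads for each of 55414 genes, not normalised. Per the submitters' processing notes, HISAT2, SAMtools, Picard, HTSeq and DESeq2 were used, with no versions or settings, and both builds GRCm38 and GRCm39 were named. Because the build behind the counts could not be settled, no coordinates are given. Whether counting used strand was not given in the sources used here. Genes that overlap a neighbour or an antisense gene can therefore share reads, and reads of near-identical gene copies can be split or lost. The last 5 lines of each table name no gene (reads without a feature, ambiguous, of low quality, not aligned or not uniquely aligned). They held 9.48% to 11.7% of all counts and were left out of library sizes and tests.

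The depth was 42718015 to 48549982 gene counts per library. Genes were kept with the default filter of edgeR by group, which left 15481. Libraries were scaled with TMM factors, 1.05 to 1.06 in untreated and 0.943 to 0.952 in TNF libraries, and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.0834. Fold changes of genes with few counts in 1 group depend on the prior count of the fit, so genes with up to 11 counts in the libraries of a group are given with those counts, as a lower bound against 3 counts over the group where they had none, or as a ratio with its exact 95% counting interval. These cover counting error only, since the reads carry no molecular identifiers. Log2 CPM values used a prior count of 2.

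Fixed before the data were examined were the test, 38 gene lists, the alternatives and the rule for the genes named. The lists cover the TNF response, cartilage, signalling, stress, metabolism, other cell types and sex-linked genes, and were written from textbook knowledge. Some genes are on 2 lists. Lists with at least 3 tested members were tested with camera of limma 3.58.1, with a preset correlation between genes of 0.01 and with an estimated one, and with fry, adjusted over all lists tested. Camera compares the members of a list with all other genes, and fry tests whether they move one way on balance. In camera, 17 lists passed with the preset correlation, and none of them passed with the estimated correlation. Fry also passed lists that camera with the preset correlation did not. Examples are hypertrophic markers (down, fry adjusted p = 1.88e-05), chondrocyte regulators (down, 0.00246), Wnt, Hedgehog and Notch signalling (down, 1.67e-06) and prostaglandin and nitric oxide synthesis (up, 7.21e-08). Single values per library were compared with exact two-sided permutation tests of 4 against 4 libraries (70 arrangements, smallest p = 0.0286).

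The rule named the 12 largest rises and 12 largest falls among genes with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between groups, without predicted genes and pseudogenes. It named 21 genes of the TNF response and of cartilage whatever their values. In each list it named up to 4 members that passed with the largest absolute change and a mean log2 CPM of at least 0, and the most expressed member that did not pass. It also named the 5 smallest p-values outside the lists and genes above 2% of a library's counts. Not every gene that the rule named is given. Genes chosen after their values were seen are named as such in the closing section.

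The steps were tested on simulated data. In 10 simulated sets of 15481 genes drawn from the libraries' means and sizes, each with 200 genes changed, the test of TNF against untreated recovered 36.6% of changes of 1.25-fold, 68.6% of 1.5-fold, 77.8% of 2-fold and 94.6% of 4-fold. These rates hold for sets with few changed genes, while 68.3% of the tested genes passed in the data, so they do not carry over to it. Of 1455 calls, 4.60% were false, and 5 of 100 lists without a change had a camera p under 0.05. The simulated genes were drawn independently of each other, so this rate does not cover lists whose genes move together. In the data the estimated correlation was 0.477 in the interferon response list and 0.694 in the list of glycolysis and hypoxia. Libraries of a group were compared pairwise before averaging: their counts differed by a chi-square of 10.7 to 42.7 per degree of freedom, so no library was a copy of another.

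Alternatives were RLE factors, library size alone, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 4 libraries, a test against a fold change of 1.5, a block by replicate number and leaving out each library in turn. For principal components they were a prior count of 0.5 and the 500 most variable genes. Gene lengths, GC content and gene types came from GENCODE M21 by gene identifier, which matched 52081 (94.0%) of the identifiers and gave a length for 99.8% of the tested genes. All samples were run in 1 pool, and the labels give no other batch.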

Results

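Chondrocytes, the cells that make and maintain cartilage, were isolated from the ends of the limb long bones of C57BL/6 mice aged 3 to 4 days and plated. One set of cultures received tumour necrosis factor alpha (TNF), an inflammatory cytokine, for 6 h after 2 h without serum, and the other received no treatment. The dose of TNF was not given in the sources used here, and the protocol text was the same for every sample, so whether untreated cells were also kept without serum could not be read from it. Messenger RNA of 4 untreated and 4 TNF-treated samples was sequenced, each named as a biological replicate. Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure the spread between these 8 libraries. Reads assigned to genes numbered 48549982, 47379430, 44082676 and 47648424 in untreated replicates 1 to 4 and 42718015, 45587656, 48543701 and 45818212 in TNF replicates 1 to 4. Between 20748 and 21808 genes had at least 1 count in a library. Expression is given as CPM, counts scaled to a common library size and normalised, mean ± SD with n = 4 per group. Changes are given as the log2 fold change of TNF against untreated ± standard error. This error was derived from the F test, as the size of the change over the square root of F. For genes with few untreated counts, such as Ccl5, H2-Q6, Mx1, Gbp5 and Cd74, it was smaller than counting error alone and overstates the precision.

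The comparison of TNF-treated with untreated cells asked how the cytokine alters gene expression in chondrocytes. After 6 h, most or all measured genes of NF-kB feedback, chemokines, interferon response, class I antigen presentation and glycolysis were higher. Most genes of the cartilage matrix were lower. These lists passed camera with the preset correlation between genes and not with an estimated one. Ccl5, a chemokine that attracts T cells and monocytes, went from 0.165 ± 0.0867 to 6913 ± 259.9 CPM, a log2 change of 15.32 ± 0.15. Counting error alone was larger than this standard error: 33 untreated counts gave a ratio of 41531 with a counting interval of 29573 to 60334. Nos2, the inducible nitric oxide synthase, went from 7 counts in the untreated libraries to 127539 in the TNF libraries, and Saa3, an acute phase protein, rose by 13.74 ± 0.36. Acan, which encodes the main proteoglycan of cartilage, fell 16.2-fold from 803.6 ± 175 to 49.7 ± 15.0 CPM. Col2a1, the type II collagen gene, fell 2.85-fold from 20181 ± 4688 to 7077 ± 1913 CPM. Of 15481 tested genes, 10570 (68.3%) passed an edgeR quasi-likelihood adjusted p of 0.05, 5305 higher and 5265 lower with TNF.

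The rises reached further than the falls. Changes of over 2-fold among the genes that passed counted 1632 higher and 1717 lower, changes of over 16-fold 325 higher and 89 lower, and changes of over 256-fold 65 higher and 1 lower. In 9780 genes (63.2%) the 4 TNF libraries did not overlap the 4 untreated libraries, against 2.86% by chance. The first principal component held 88.8% of the variance and separated the groups (exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 libraries can give), and the second held 3.11%. The balance of directions depended on scaling: with library size alone every change lay 0.16 lower on the log2 scale at the median, and 34.4% of the changed genes were higher in place of 50.2%. The 10 most abundant genes took 13.2% to 13.9% of counts in untreated and 9.33% to 9.95% in TNF libraries. Changes below are relative to the trimmed mean (TMM) scaling.

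**Figure D1:**
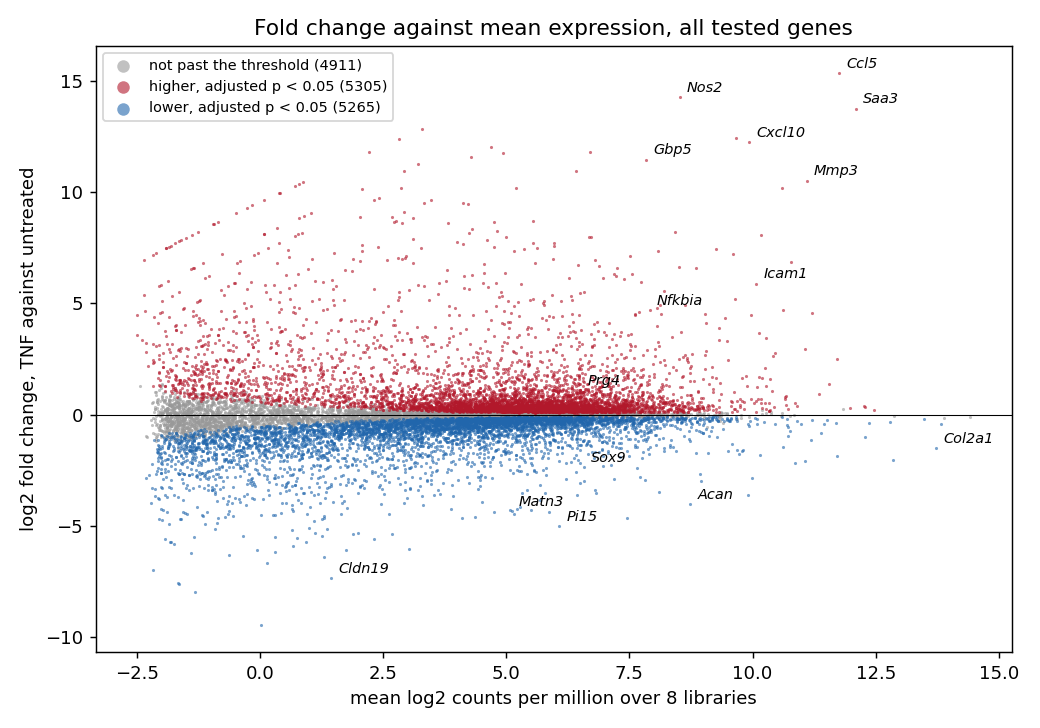
Log2 fold change of TNF against untreated (vertical axis) against mean log2 CPM over the 8 libraries (horizontal axis), 1 point per tested gene, red for 5305 genes that were higher and blue for 5265 that were lower at an adjusted p under 0.05, grey for the rest. Ccl5 lies at 15.32 and Cldn19, the lowest gene named, at -7.35 (from 5 counts in the TNF libraries), relative to TMM scaling.

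Of the 12 largest rises among well expressed genes, 5 belonged to genes with 0 to 3 counts in the untreated libraries. Heatr9 had no count in the 4 untreated libraries and 3430 in the 4 TNF libraries, at least 1314-fold higher against a floor of 3 counts over the untreated group. Madcam1, an adhesion molecule for lymphocytes, also had no untreated count and was at least 948-fold higher. Spib, an ETS transcription factor, had 2 untreated counts, a ratio of 5191 (95% counting interval 1437 to 42870). Acod1, which makes itaconate, had 3 untreated counts, a ratio of 4079 (95% counting interval 1395 to 19783). Oas3, an interferon-induced sensor of double-stranded RNA, had 1 untreated count, a ratio of 3710 (95% counting interval 665 to 146569). These intervals and floors cover counting error only. The other 7 were Ccl5, Nos2, Saa3, Cxcl9, Cxcl10, Cxcl2 and Gbp5. The smallest p-values outside all gene lists belonged to Stx11 (4.39 ± 0.04), Il18bp (6.37 ± 0.07), Ifi44 (5.94 ± 0.07), Gbp6 (7.98 ± 0.10) and Phf11d (5.51 ± 0.07), all higher with TNF. Il18bp encodes a secreted inhibitor of interleukin 18.

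Of the 12 largest falls, Cldn19 had 5 counts in the TNF libraries, a ratio of 0.00563 (95% counting interval 0.00182 to 0.0132). Serpinb5 had 9, a ratio of 0.0114 (95% counting interval 0.00518 to 0.0217). The others were Galnt9 (-6.06 ± 0.44), Slc16a14 (-6.06 ± 0.29), Gask1a (-5.60 ± 0.35), Sv2c (-5.45 ± 0.39), Adh1 (-5.36 ± 0.36), Ncmap (-5.36 ± 0.30), Gsg1l (-5.31 ± 0.25), Cidec (-5.31 ± 0.19), Pi15 (-5.01 ± 0.11) and Vwc2 (-4.78 ± 0.30). The most abundant of them was Pi15, which went from 130.2 ± 17.4 to 4.04 ± 0.434 CPM. The other 11 lay between 3.89 and 15.6 CPM in untreated cells.

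Genes of the NF-kB pathway rose together. NF-kB is the transcription factor family through which TNF acts on many of its target genes. In the list of its subunits and feedback regulators, 21 of 21 genes rose, with a median log2 change of 3.04 (camera adjusted p = 7.26e-13, and adjusted p = 0.0739 with an estimated correlation). Nfkbia, the inhibitor that retains NF-kB in the cytoplasm, rose from 18.03 ± 1.27 to 463.9 ± 20.3 CPM (4.69 ± 0.06), Tnfaip3, the A20 deubiquitinase, by 6.97 ± 0.10, Traf1 by 5.90 ± 0.09 and Nfkbie by 5.45 ± 0.09. Of 14 TNF receptors and adaptors, 12 rose, 1 fell and 1 did not pass, with a median of 0.44 (camera adjusted p = 0.000317, and adjusted p = 0.0739 with an estimated correlation). Tnfrsf1b rose by 2.19 ± 0.07, Adam17, the protease that sheds TNF, by 1.94 ± 0.04, Traf3 by 1.56 ± 0.05 and Traf5 by 1.13 ± 0.11, while Tradd was at 0.06 ± 0.07. Tnfrsf1a, the receptor that most cells carry, rose by 0.18 ± 0.07 (174.4 ± 18.4 to 197.6 ± 7.97 CPM, edgeR adjusted p = 0.0347). That call ended with library size alone (0.02, adjusted p = 0.819) and without untreated replicate 2 (0.0901), 3 (0.0795) or 4 (0.103) or TNF replicate 2 (0.0845) or 4 (0.0578).

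Chemokines had the largest median rise of all lists. Of 20 measured chemokines, 19 rose and none fell (1 fell with library size alone), with a median of 7.33 (camera adjusted p = 5.01e-09, and adjusted p = 0.185 with an estimated correlation). After Ccl5, the largest were Cxcl9 (12.42 ± 0.20), Cxcl10 (12.22 ± 0.23) and Cxcl2 (11 untreated counts, a ratio of 3787, 95% counting interval 2116 to 7586). Ccl2, which attracts monocytes, went from 2.64 ± 1.43 to 3082 ± 185 CPM, and Cxcl1, which attracts neutrophils, from 2.36 ± 0.346 to 690.5 ± 41.7 CPM. Cxcl14 stood at -0.41 ± 0.19 and did not pass (edgeR adjusted p = 0.0809). It passed without untreated replicate 4 (0.0318) or TNF replicate 2 (0.0348), with library size alone (0.0193) and with no filter on low counts (0.0281). Of 17 measured inflammatory cytokines and growth factors, 13 rose and none fell (1 fell with library size alone), with a median of 3.96 (camera adjusted p = 7.26e-05, and adjusted p = 0.185 with an estimated correlation). Il6 rose by 7.03 ± 0.42, from 0.104 ± 0.0987 to 14.1 ± 4.55 CPM, and Tnf itself by 5.20 ± 0.35, to 4.55 ± 1.37 CPM. Csf2 had no untreated count and was at least 178-fold higher against the floor of 3 counts. Csf3 had 2 untreated counts, a ratio of 368 (95% counting interval 101 to 3044). Il1rn, the interleukin 1 receptor antagonist, stood at 155.5 ± 76.5 CPM untreated and 133.8 ± 28.2 CPM with TNF (edgeR adjusted p = 0.584, and 0.0332 without untreated replicate 4). The medians of the chemokine, cytokine and adhesion lists were the same with the 1 member of each that had no untreated count set to its bound. Reads of the Ccl, Cxcl, Gbp, Saa and H2-Q families can be shared between similar copies, so the split of counts between their members is uncertain.

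Interferon response genes rose in every case. All 30 measured members were higher, with a median of 5.09 (camera adjusted p = 1.56e-16, and adjusted p = 0.185 with an estimated correlation). Examples are Gbp5 (11.45 ± 0.17), a guanylate-binding protein, Oas1a (7.84 ± 0.18), Mx1 (7.66 ± 0.15) and Zbp1 (7.56 ± 0.16), a nucleic acid sensor. All 18 genes of class I antigen presentation rose, with a median of 3.63 (camera adjusted p = 1.38e-13, and adjusted p = 0.0977 with an estimated correlation), among them H2-Q6 (8.27 ± 0.14), H2-Q7 (6.77 ± 0.12), H2-Q4 (6.58 ± 0.06) and the immunoproteasome subunit Psmb8 (6.68 ± 0.14). In the list of cell adhesion and innate sensing, 19 of 20 rose and none fell, with a median of 2.78 (camera adjusted p = 1.88e-09, and adjusted p = 0.0678 with an estimated correlation). Icam1 went from 35.9 ± 1.55 to 2123 ± 202 CPM, Nod2 rose by 6.82 ± 0.18 and Ripk2 by 4.62 ± 0.08, while Il18r1 stood at 0.47 ± 0.57. Of 15 measured complement genes, 8 rose, 3 fell and 4 did not pass, with a median of 0.96 (camera adjusted p = 0.113). C3, the central complement component, rose by 6.85 ± 0.25 to 3475 ± 403 CPM, Cfb by 6.26 ± 0.17, C2 by 3.88 ± 0.12 and C1s1 by 2.69 ± 0.07, and C1qb stood at -0.27 ± 0.38. The complement list passed without TNF replicate 1 (0.0446) and with library size alone (0.017).

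Nitric oxide and prostaglandin synthesis changed in both directions. All 13 measured genes changed, 9 higher and 4 lower, with a median of 0.78. The member that fell most changed by -4.67. The list just missed the threshold (camera adjusted p = 0.0524) and passed it without untreated replicate 1 (0.0482), 2 (0.0359) or 3 (0.0485), or without TNF replicate 1 (0.0446) or 2 (0.0451). Nos2 had 7 untreated counts in all and reached 736.2 ± 82.8 CPM with TNF, a ratio of counts of 20945 (95% counting interval 10165 to 52097). Ptgs2, the inducible cyclooxygenase, rose by 5.02 ± 0.20 and Gch1, which makes the cofactor of nitric oxide synthase, by 5.06 ± 0.06. Arg2 had 6 untreated counts, a ratio of 139 (95% counting interval 63.6 to 380).

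Several proteases that cut the cartilage matrix were higher. Mmp3 (stromelysin 1) went from 2.99 ± 1.22 to 4388 ± 698 CPM (10.51 ± 0.27), and Mmp13, a collagenase of cartilage, from 86.8 ± 24.7 to 1931 ± 211 CPM (4.48 ± 0.19). Adamts4 rose by 1.63 ± 0.14, from 16.2 ± 3.80 to 50.2 ± 3.04 CPM, and Adamts5 by 0.86 ± 0.06, from 303.7 ± 23.5 to 551.4 ± 23.3 CPM; both encode aggrecanases. Mmp9 rose by 7.35 ± 0.23 and Mmp10 by 4.78 ± 0.25, while Htra1 stood at -0.02 ± 0.07 and passed only with library size alone (-0.18, adjusted p = 0.0392). Over the list of 24 matrix proteases 14 rose, 6 fell and 4 did not pass, or 12 rose and 8 fell with library size alone, with a median of 0.40 that was then 0.24 (camera adjusted p = 0.0388). The call ended without untreated replicate 4 (0.0656) and with at least 1 CPM in 4 libraries (0.0524), and it had an adjusted p = 0.613 with an estimated correlation. Of 14 measured protease inhibitors 7 rose, 6 fell and 1 did not pass, with a median of 0.18 (camera adjusted p = 0.902). Timp1 rose by 2.84 ± 0.16, from 131 ± 31.4 to 935.5 ± 134 CPM, Tfpi2 by 2.93 ± 0.31 and A2m by 2.79 ± 0.18. Serpinf1 stood at -0.15 ± 0.08 (edgeR adjusted p = 0.135, 0.0111 without untreated replicate 4 and 0.00556 with library size alone).

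Genes of the cartilage matrix were lower. Of 25 members 22 fell, 2 rose (1 with library size alone) and 1 did not pass, with a median of -1.62 (camera adjusted p = 6.51e-06, and adjusted p = 0.347 with an estimated correlation). Matn3, a matrilin of the cartilage matrix, changed by -4.35 ± 0.12, Acan by -4.02 ± 0.23, Col27a1 by -3.40 ± 0.14 and Snorc by -3.17 ± 0.30. Col2a1 changed by -1.51 ± 0.20 (edgeR adjusted p = 4.29e-05), and its share of all gene counts went from 2.13% ± 0.497 to 0.669% ± 0.184. Lum, a small leucine-rich proteoglycan also made by fibroblasts, stood at -0.14 ± 0.15. Among 24 measured genes of glycosaminoglycan and hyaluronan synthesis 17 fell, 3 rose and 4 did not pass, with a median of -0.36 (camera adjusted p = 0.00694, and adjusted p = 0.185 with an estimated correlation). Csgalnact1 changed by -1.25 ± 0.08, the hyaluronan synthase Has2 by -1.21 ± 0.07 and Cemip, which acts in hyaluronan breakdown, by -1.20 ± 0.11. The sulfotransferase Chst15 rose by 2.45 ± 0.09. The list also holds hyaluronidases, so its counts do not give synthesis alone. Chpf stood at 0.05 ± 0.06 (edgeR adjusted p = 0.416, and 0.0456 without TNF replicate 3).

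**Figure D2:**
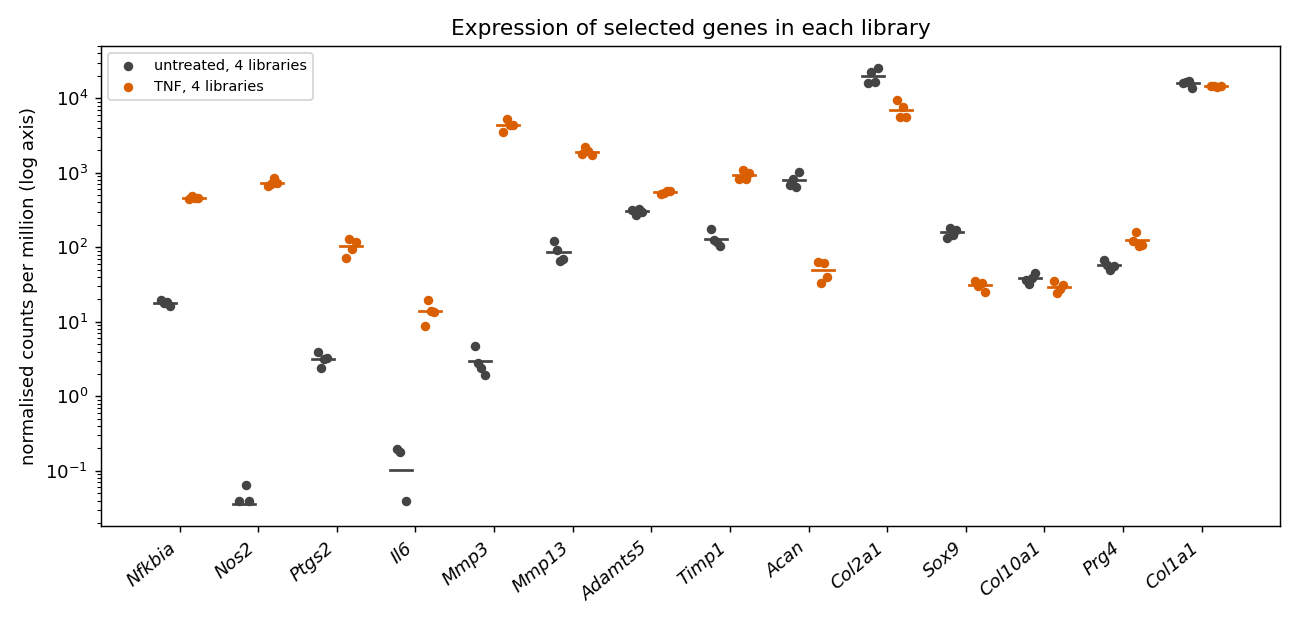
Normalised CPM (vertical axis, log scale) of 14 genes in each library, grey points for the 4 untreated and orange points for the 4 TNF libraries, with a line at each group's mean and libraries at 0 not drawn. Acan lay at 803.6 CPM on average in untreated and 49.7 CPM in TNF libraries, and Mmp3 at 2.99 and 4388 CPM, while Col1a1 did not pass the test.

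Chondrocyte regulators moved in both directions. Sox9, the transcription factor that directs chondrocyte identity and switches on Col2a1 and Acan, fell 5.14-fold from 159.8 ± 22.7 to 31.1 ± 4.38 CPM (-2.36 ± 0.12). Fgfr3, a receptor that restrains chondrocyte proliferation, changed by -2.72 ± 0.16, whereas Bmpr1b rose by 2.06 ± 0.07 and Pthlh by 3.71 ± 0.26. Of 19 measured regulators 11 fell, 6 rose and 2 did not pass, with a median of -0.61 (camera adjusted p = 0.204). Zbtb20 stood at -0.27 ± 0.16 (edgeR adjusted p = 0.146, 0.0198 without TNF replicate 3 and 0.026 with library size alone). Of 16 measured markers of hypertrophic chondrocytes 10 fell, 5 rose and 1 did not pass, with a median of -1.23 (camera adjusted p = 0.162). Ibsp changed by -3.31 ± 0.26, Sp7 by -3.03 ± 0.26 and Dlx5 by -2.38 ± 0.15, Phospho1 stood at 0.46 ± 0.31, and Mmp13 is also on this list. Col10a1, the collagen of hypertrophic cartilage, changed by -0.37 ± 0.12, from 38.3 ± 5.86 to 29.7 ± 4.799 CPM (edgeR adjusted p = 0.0214). That call ended without untreated replicate 4 (0.0563) or TNF replicate 2 (0.0586) or 3 (0.0613). Ihh was too low to be tested, with 31 counts in the untreated and 6 in the TNF libraries, a ratio of 0.222 (95% counting interval 0.0759 to 0.541).

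Of 17 markers of the superficial and articular zone 11 were higher and 6 lower, or 7 higher and 6 lower with library size alone. Prg4, which encodes the joint lubricant lubricin, rose from 57.7 ± 7.68 to 123.9 ± 26.0 CPM (1.10 ± 0.13), and the hyaluronan receptor Cd44 by 2.96 ± 0.08. Sfrp2, an inhibitor of Wnt signalling, changed by -2.85 ± 0.18, from 1784 ± 412 to 247 ± 40.1 CPM, the transcription factor Erg by -2.23 ± 0.06 and Tppp3 by -1.68 ± 0.29. The list median was 0.59, its mean 0.06 and the direction of the rotation test fry down (camera adjusted p = 0.662, fry adjusted p = 0.742). In the list of fibrillar and fibroblast matrix 8 of 20 rose, 4 fell and 8 did not pass, or 5 rose and 7 fell with library size alone (camera adjusted p = 0.773). Its median was 0.01, its mean -0.02, and its median -0.15 with library size alone. Eln changed by -1.44 ± 0.18 and Thy1 by -1.33 ± 0.15, while Pdgfra rose by 1.248 ± 0.13 and Fbn1 by 0.69 ± 0.20. Fn1, the most abundant gene, took 2.41% ± 0.153 of untreated and 1.97% ± 0.370 of TNF counts (-0.13 ± 0.12, edgeR adjusted p = 0.357, 0.0399 without TNF replicate 3 and 0.0405 with library size alone). Col1a1 stood at 15928 ± 1384 CPM untreated and 14436 ± 331 CPM with TNF (-0.14 ± 0.07, edgeR adjusted p = 0.0768). It passed without untreated replicate 4 (0.00314), with library size alone (0.00138), with DESeq2 (0.0497) and with no filter on low counts (0.0356).

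In both lists of signalling in cartilage growth most members were lower. The lists hold activators and inhibitors of each pathway, so these counts do not give pathway activity. Of 28 genes of bone morphogenetic protein (BMP) and TGF-beta signalling 19 fell, 8 rose and 1 did not pass, with a median of -0.64 (camera adjusted p = 0.0139). The call ended with library size alone (0.0953) and had an adjusted p = 0.185 with an estimated correlation. Id1, a direct target of BMP signalling, fell 11.4-fold from 101 ± 15.0 to 8.86 ± 2.14 CPM, Id4 changed by -2.92 ± 0.09 and Smad9 by -2.53 ± 0.10, while the ligand Bmp2 rose by 2.82 ± 0.11 and Bmpr2 stood at -0.02 ± 0.08. Of 27 measured genes of Wnt, Hedgehog and Notch signalling 15 fell, 7 rose and 5 did not pass, with a median of -0.53 (camera adjusted p = 0.113). Frzb, a Wnt antagonist of cartilage, changed by -3.62 ± 0.13, Nkd1 by -2.24 ± 0.09, Hes1 by -1.89 ± 0.28 and Gli2 by -1.84 ± 0.07, and Axin2 stood at -0.18 ± 0.11 and passed only with library size alone (-0.34, adjusted p = 0.015). Of 25 immediate early genes 16 rose, 7 fell and 2 did not pass, with a median of 0.68 (camera adjusted p = 0.0311, and adjusted p = 0.377 with an estimated correlation). Fosl1 rose by 4.64 ± 0.14, Ier3 by 3.63 ± 0.08, Maff by 3.46 ± 0.09 and Cebpb by 2.08 ± 0.08, while Jun stood at -0.07 ± 0.07 and passed only with library size alone (-0.23, adjusted p = 0.0104).

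All 23 genes of glycolysis and hypoxia rose, with a median of 1.75 (camera adjusted p = 1.89e-11, and adjusted p = 0.252 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 5.38 ± 0.14, the lactate transporter Slc16a3 by 3.69 ± 0.16, the hexokinase Hk2 by 2.67 ± 0.07 and Bnip3 by 2.61 ± 0.09. Of 23 genes of oxidative and metal stress 20 rose, 2 fell and 1 did not pass, with a median of 2.08 (camera adjusted p = 1.59e-07, and adjusted p = 0.231 with an estimated correlation). Besides Saa3, which reached 8795 ± 1011 CPM, Lcn2 rose by 7.22 ± 0.17, the metallothionein Mt2 by 4.33 ± 0.09 and the superoxide dismutase Sod2 by 3.48 ± 0.05, and Cat stood at 0.08 ± 0.06. Of 20 measured genes of apoptosis and survival 14 rose, 2 fell and 4 did not pass, or 13 rose and 4 fell with library size alone, with a median of 0.61 (camera adjusted p = 0.000609, and adjusted p = 0.185 with an estimated correlation). Casp4, the inflammatory caspase 11, rose by 5.27 ± 0.18, the death receptor Fas by 3.17 ± 0.05 and Bid by 3.09 ± 0.06, and these promote cell death. Xiap, an inhibitor of caspases, stood at -0.08 ± 0.04 (edgeR adjusted p = 0.11, 0.028 without TNF replicate 3 and 0.000361 with library size alone).

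Proliferation, endoplasmic reticulum stress and cholesterol synthesis did not pass camera as groups. By fry, endoplasmic reticulum stress (up, adjusted p = 0.000115) and cholesterol synthesis (up, 0.00246) passed, and the cell cycle list (0.105) did not. Of 27 cell cycle genes 10 rose, 7 fell and 10 did not pass, or 6 rose and 12 fell with library size alone, with a median of 0.07 that was then -0.09 (camera adjusted p = 0.758). Ccnd1 rose by 1.22 ± 0.05, while Cdc20 changed by -0.97 ± 0.11, Ccnb2 by -0.85 ± 0.13 and Ccnb1 by -0.74 ± 0.14, and Top2a stood at 0.18 ± 0.12. Of 20 genes of endoplasmic reticulum stress 12 rose, 4 fell and 4 did not pass (12 and 5 adjusted over the list alone), or 7 rose and 6 fell with library size alone, with a median of 0.17 that was then 0.01 (camera adjusted p = 0.113). Sdf2l1 rose by 0.84 ± 0.05 and Calr by 0.83 ± 0.05, Chac1 changed by -0.87 ± 0.09 and Creb3l2 by -0.78 ± 0.05, and Xbp1 stood at 0.08 ± 0.04. Of 20 genes of cholesterol synthesis 9 rose, 1 fell and 10 did not pass (8 and 1 adjusted over the list alone), or 7 rose and 4 fell with library size alone, with a median of 0.13 that was then -0.03 (camera adjusted p = 0.0678). Stard4 rose by 1.12 ± 0.04, and Hmgcs1 stood at -0.09 ± 0.06 and passed only with library size alone (-0.25, adjusted p = 0.00198). The cholesterol list passed without untreated replicate 1 (0.0302) or TNF replicate 1 (0.0389). For all lists in which no second pair of counts is given, the counts adjusted over the list alone were the same as those over all genes tested.

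**Figure D3:**
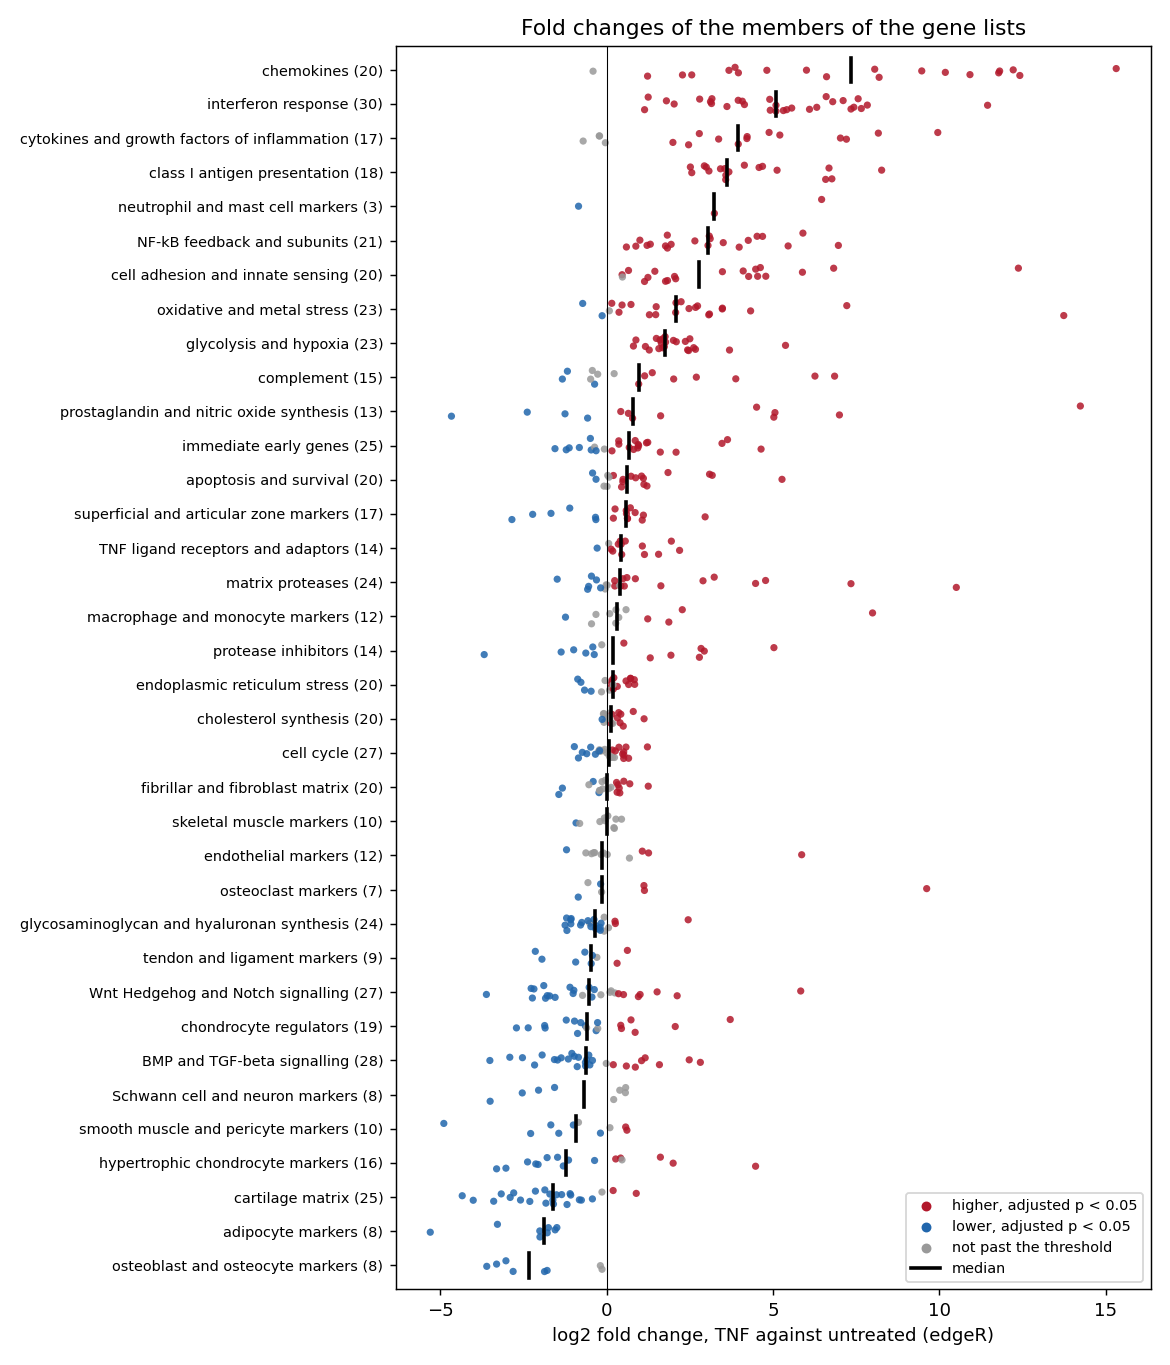
Log2 fold change of TNF against untreated (horizontal axis) of each tested member of the gene lists, 1 line of points per list with the number of measured members in brackets, red and blue for members higher and lower at an adjusted p under 0.05, grey for the rest, and a black bar at the median. The interferon response list has a median of 5.09 and the cartilage matrix list of -1.62, and with library size alone the medians of the cell cycle, cholesterol and fibrillar lists turn to -0.09, -0.03 and -0.15 and all medians lie 0.16 lower.

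Markers of other cell types that a preparation from bone ends can hold had medians below 0 in the lists of adipocytes, osteoblasts, smooth muscle, tendon and Schwann cells. All 8 measured adipocyte markers fell, with a median of -1.90 (camera adjusted p = 0.000131, and adjusted p = 0.26 with an estimated correlation), Cidec most, then Retn (-3.29 ± 0.21), Pparg (-2.01 ± 0.14) and Plin1 (-2.01 ± 0.12). Of 8 measured osteoblast and osteocyte markers 6 fell and none rose, with a median of -2.34 (camera adjusted p = 0.0034, and adjusted p = 0.14 with an estimated correlation), such as Phex (-3.61 ± 0.24) and Alpl (-1.79 ± 0.19). Of 10 smooth muscle and pericyte markers 6 fell and 2 rose (1 with library size alone), with a median of -0.93 (camera adjusted p = 0.162). Cnn1 changed by -2.29 ± 0.22, Cspg4 by -1.68 ± 0.09, Myh11 by -1.44 ± 0.42 and Rgs5 by -1.005 ± 0.19, and Notch3 stood at 0.10 ± 0.24. Of 9 tendon and ligament markers 6 fell and 2 rose, or 7 fell and none rose with library size alone, with a median of -0.47 (camera adjusted p = 0.0951). Mkx changed by -2.15 ± 0.09, Kera by -1.95 ± 0.35, Scx by -0.93 ± 0.05 and Thbs2 by -0.66 ± 0.11. Tnmd stood at -0.30 ± 0.14 (edgeR adjusted p = 0.0854) and passed without untreated replicate 4 (0.0282) or TNF replicate 4 (0.0167), with library size alone (0.013) and with no filter (0.0302). Of 8 measured Schwann cell and neuron markers 4 fell and none rose, with a median of -0.68 (camera adjusted p = 0.343). Prph changed by -3.51 ± 0.26, S100b, which chondrocytes also express, by -2.54 ± 0.17 and Ngfr by -1.57 ± 0.38. Tubb3 stood at 0.39 ± 0.20 (edgeR adjusted p = 0.107, and 0.0216 without untreated replicate 1).

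Blood and vessel markers gave mixed results. Of 12 measured macrophage and monocyte markers 4 rose, 1 fell and 7 did not pass, with a median of 0.32 and a mean of 1.08 (camera adjusted p = 0.394). Cd74, the invariant chain of class II antigen presentation, rose by 7.99 ± 0.12 from 0.248 ± 0.0628 CPM, Adgre1 by 2.27 ± 0.41 and Csf1r by 1.87 ± 0.28, while Mrc1 changed by -1.24 ± 0.25. Lyz2, the most abundant, stood at 53.0 ± 13.2 CPM untreated and 63.9 ± 25.1 CPM with TNF (edgeR adjusted p = 0.412, and 0.0327 without TNF replicate 1). Of 13 neutrophil and mast cell markers 3 were measured, 2 higher and 1 lower, with a median of 3.24 (camera adjusted p = 0.343), and Camp rose by 6.46 ± 0.24. Of 7 measured osteoclast markers 3 rose, 2 fell and 2 did not pass (3 and 3 adjusted over the list alone), or 3 rose and 4 fell with library size alone, with a median of -0.15 and a mean of 1.44 (camera adjusted p = 0.812). Calcr had 2 untreated counts, a ratio of 1005 (95% counting interval 278 to 8303), Acp5 rose by 1.13 ± 0.13, and Itgb3 changed by -0.86 ± 0.10 and Ctsk by -0.18 ± 0.05. Nfatc1 stood at -0.15 ± 0.07 (edgeR adjusted p = 0.0587) and passed without untreated replicate 1 (0.0388) or 3 (0.0374) or TNF replicate 1 (0.0456), with library size alone (0.00117), with no filter (0.048) and with at least 1 CPM in 4 libraries (0.0415). Of 12 measured endothelial markers 3 rose, 1 fell (2 with library size alone) and 8 did not pass, with a median of -0.13 and a mean of 0.46 (camera adjusted p = 0.727). Flt1, a receptor for vascular endothelial growth factor, rose by 5.86 ± 0.17, Eng by 1.26 ± 0.13 and Plvap by 1.07 ± 0.24, and Tek changed by -1.21 ± 0.21. Egfl7 stood at -0.46 ± 0.21 (edgeR adjusted p = 0.0798, 0.0438 without TNF replicate 2 and 0.023 with library size alone). Of 10 measured skeletal muscle markers 1 fell and none rose (none of either adjusted over the list alone), with a median of -0.01 that was above 0 with RLE scaling (camera adjusted p = 0.86). Tnnt3 changed by -0.92 ± 0.27 and Acta1 stood at -0.21 ± 0.27. None of the 10 erythroid markers had enough counts to be tested. Of the sex-linked genes Xist was not tested and 4 were measured. Ddx3y rose by 0.20 ± 0.04 with TMM scaling and not with library size alone (0.03, adjusted p = 0.468), Kdm5d changed by -0.24 ± 0.06 and Eif2s3y by -0.25 ± 0.08, a call that ended without untreated replicate 2 (0.0541). Uty stood at 0.11 ± 0.05 (edgeR adjusted p = 0.0689, and 0.0129 without TNF replicate 3), and 2 and 2 of these genes passed adjusted over the list alone.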

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

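In groups of 4 libraries, a result stood out where the gap between the highest or lowest library and its neighbour took more than 0.829 of the group's range, a limit that chance passes in about 1 of 20 groups. Of 526 groups of gene, list and library values looked at, 33 (6.27%) passed it, close to that share. The number given with each result is this share of the range.

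Untreated replicate 4 was the lowest of its group in 7 of the 33, more than any other library. Of these, Acod1 (0.949) had at most 1 untreated count per library and says nothing beyond counting error. The library's score of the interferon response list, the mean log2 CPM of the members centred over the 8 libraries, was -2.92 against -2.41, -2.40 and -2.42 in untreated replicates 1 to 3 (0.972). Of single genes it was lowest for Icam1 (0.954), C1qb (0.921), Zbp1 (0.882), Csf1r (0.868) and C3 (0.858), and it was highest for A2m (0.912). No explanation was tested. Leaving this library out left 10273 genes changed, and the calls that it decided are given beside the results.

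In the other untreated libraries, replicate 3 was lowest for Bid (0.977) and H2-Q6 (0.977) and highest for Mx1 (0.860), and replicate 2 was highest for Ifi44 (0.840). Replicate 2 also had the highest share of ambiguous reads, 4.24% against 2.83% to 2.97% (0.903). Spib, Calcr, Csf3, Oas3 and Xist had counts in only 1 untreated library each, of at most 4, which gives a share of 1 for each of them and says nothing beyond counting error.

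In the TNF libraries, replicate 1 was lowest for C1qb (0.908), Il18r1 (0.898), Csf3 (0.893) and Adgre1 (0.876) and highest for Id1 (0.860) and Cd44 (0.833). Replicate 2 was lowest for Slc16a14 (0.880) and Gbp6 (0.876) and highest for Hes1 (0.881), Acp5 (0.847) and Vwc2 (0.842). Replicate 3 was highest for Cldn19 (0.912), which had 5 counts in the 4 TNF libraries, and lowest for Chpf (0.875). Replicate 4 was highest for Cxcl1 (0.960) and for the score of the tendon list (0.836). Slc16a14, Vwc2 and Il18r1 in the TNF libraries and H2-Q6 and Mx1 in the untreated libraries had at most 15 counts in a library, so counting error can give their shares.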

How the results depend on the processing

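All settings here were planned. The 10570 genes called became 10592 with RLE factors, 10911 with library size alone, 10568 with DESeq2, 10586 with limma-voom, 10984 with no filter on low counts, 9544 with at least 1 CPM in 4 libraries, and 10110 to 10445 without a single library. Library size alone called 9016 (85.3%) of the genes again, none with the opposite sign, and 34.4% of its calls were higher, 3751 against 7160 lower, so the balance of directions, unlike most calls, depends on the scaling. Against a fold change of 1.5, 3972 genes remained, 1971 higher and 2001 lower, because that test asks for more. Among the 35 splits of the libraries into 4 and 4, only the real one gave as many genes, and the highest other split gave 0 at the adjusted threshold (39 to 961 at an unadjusted p under 0.05). The real split is 1 of 35 (0.0286), the smallest value that this number of splits can give. Every other split mixes treated and untreated libraries, so a strong effect widens the spread within its groups and leaves few calls. The count of 0 in those splits therefore does not exclude chance. The groups separated on the first component with 87.1% of the variance at a prior count of 0.5, 98.1% with the 500 most variable genes and 87.9% to 89.0% without a single library.

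Equal replicate numbers did not pair the libraries: the correlations of their deviations were -0.20, 0.05, -0.03 and -0.04, and 0 of 8 libraries correlated best with its own number. With a replicate block 10151 genes passed, 10077 of them also without it, and the calls of matrix proteases (adjusted p = 0.0506) and immediate early genes (0.0506) ended.

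No list that passed in either setting turned direction in camera. Turns of lists that passed in neither were not counted. Counts within lists that moved by over 1.5 times with library size alone are given beside the results. With library size alone the calls of prostaglandin and nitric oxide synthesis (0.00741) and complement (0.017) appeared and that of BMP and TGF-beta signalling ended (0.0953). Prostaglandin and nitric oxide synthesis also passed with DESeq2 (0.0335), with at least 1 CPM in 4 libraries (0.0272), where matrix proteases did not (0.0524), and with no filter (0.0153). With no filter complement (0.0214), Wnt, Hedgehog and Notch signalling (0.0245), endoplasmic reticulum stress (0.0454), cholesterol synthesis (0.0153) and tendon markers (0.0289) passed too. Without single libraries the adjusted p of prostaglandin and nitric oxide synthesis ranged from 0.0359 to 0.0611, of cholesterol synthesis from 0.0302 to 0.116, of complement from 0.0446 to 0.146 and of matrix proteases from 0.0212 to 0.0656. With an estimated correlation all 17 calls ended: NF-kB 0.0739, TNF receptors 0.0739, chemokines 0.185, cytokines 0.185, matrix proteases 0.613, cartilage matrix 0.347, class I 0.0977, interferon response 0.185, adhesion and sensing 0.0678, apoptosis 0.185, oxidative stress 0.231, immediate early genes 0.377, BMP and TGF-beta 0.185, glycosaminoglycan synthesis 0.185, glycolysis 0.252, osteoblast 0.14 and adipocyte markers 0.26. The cause of these changes was not tested.

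Of 3190 values of named genes under the alternatives, 3132 kept their side of the threshold, 17 no longer passed and 40 newly passed. The other 1, that of Impact with library size alone (-0.062), turned direction. Turns of genes that passed in neither setting were not counted. The cause of the turn of Impact was the lower scaling of all genes in that alternative. Simulated changes of 1.5-fold were recovered in 68.6% of cases, in sets with 200 changed genes against 10570 called in the data. The rate therefore does not describe this comparison, and how many small changes were missed was not measured.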

Other observations

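The tests in this part were chosen after the results were seen, except the correction for transcript length and GC content and the test of the imprinted genes not looked at before. Genes of class II antigen presentation, a pathway usually confined to specialised immune cells, were chosen as a group after their values were seen, so a test of them as a group would restate what was seen and is not used here. Of them only Cd74 was on a list fixed before, that of macrophage and monocyte markers. Of 6 measured genes 5 were higher with TNF. H2-Aa rose by 5.97 ± 0.29 on the log2 scale to 4.90 ± 0.467 CPM, H2-Ab1 by 3.24 ± 0.17 to 15.2 ± 2.57 CPM, H2-Eb1 by 1.68 ± 0.20 and H2-DMb1 by 0.53 ± 0.11, besides Cd74 at 63.6 ± 5.95 CPM. H2-DMa stood at 0.15 ± 0.13. Their master regulator Ciita was too low to be tested, with 16 counts in the untreated and 33 in the TNF libraries.

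Of other single genes chosen after their values were seen, Ch25h, which makes 25-hydroxycholesterol, was higher by 7.998. Ccn2, a matrix protein of growing cartilage, changed by -3.62 and Lgr5, a receptor that enhances Wnt signalling, by -4.13. The clock gene Dbp changed by -2.14 and Idh1 by -1.01. The list of superficial and articular markers had 11 higher and 6 lower genes, and the cartilage matrix list 2 higher and 22 lower, or 7 and 6 against 1 and 22 with library size alone. With TMM scaling their balance differed (Fisher's exact test across genes, which are not independent replicates, two-sided p = 0.000344, adjusted over 3 such contrasts 0.00103). The contrast was chosen after these counts were seen, so the test restates them and adds no independent evidence. The balance of the superficial list did not differ detectably from that of the hypertrophic list (Fisher's exact p = 0.156, adjusted 0.156), nor that of the cartilage matrix from the hypertrophic list (Fisher's exact p = 0.0846, adjusted 0.127).

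Imprinted genes, which are expressed from 1 parental copy and many of which promote fetal growth, were seen among the falls. H19 changed by -2.06 ± 0.10, from 3461 ± 329 to 828.9 ± 107 CPM, Igf2 by -1.83 ± 0.11, Mest by -1.82 ± 0.16, Peg3 by -2.66 ± 0.13, Peg10 by -2.01 ± 0.08, Cdkn1c by -2.89 ± 0.16 and Zim1 by -3.40 ± 0.13. The hypothesis that imprinted genes fall as a group was then tested on other imprinted genes not looked at before. Whether those are regulated together with the genes above was not tested, so they may not be independent of them. Of 22 measured, 14 were lower, 2 higher (Ascl2 by 3.80 and Impact by 0.10) and 6 did not pass, with a median of -0.57 (camera p = 0.000783, and p = 0.0266 with an estimated correlation, both unadjusted). With an estimated correlation, unadjusted camera p-values were smaller for adhesion and sensing (0.00183) and NF-kB (0.00573). Neither of those lists passed after adjustment over all lists, so 0.0266 does not set the imprinted genes apart from them. The call of Impact was not stable: it ended without untreated replicate 2 (adjusted p = 0.0663), 3 (0.0892) or 4 (0.0796), without TNF replicate 1 (0.0641) or 3 (0.0564) and with no filter (0.11), and its change was -0.062 with library size alone (0.157). This is consistent with a fall of imprinted genes as a group in TNF-treated cells, as a hypothesis found and tested in the same libraries, and an effect through the growth state of the cells stays untested.

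The rise of 30 of 30 interferon response genes in cultures treated with TNF was looked at for its source. A higher share of immune cells in the TNF libraries was tested with 12 of 15 macrophage and monocyte markers, none of which is on the interferon list. Their median was 0.319 with an SD of 2.39 against 5.09 for the interferon list, and the abundant marker Lyz2 went from 53.0 to 63.9 CPM (a change that passed only without TNF replicate 1, adjusted p = 0.0327). Other markers rose, Cd74 by 7.99, Adgre1 by 2.27 and Csf1r by 1.87, as did the neutrophil marker Camp by 6.46, while Mrc1 changed by -1.24. The median lay below that of the interferon list by more than the spread of the markers, which argues against more immune cells as the whole source, and a change in the number or state of such cells stays open. Interferon beta made in the treated cultures may contribute, since Ifnb1 had 2, 1, 1 and 5 counts in the 4 TNF libraries, 9 in all, and none in the untreated libraries, while 11 of 12 interferon ligand genes had no count in any of the 8 libraries. Whether so few transcripts suffice, or TNF acts on these genes directly, was not tested and stays open. An effect of serum cannot be told apart from TNF if the untreated cells kept theirs.

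The fall of cartilage matrix genes was weighed against a lower share of chondrocytes in the TNF libraries. A lower share alone, with no gene changed within cells, would raise markers of other cell types alike, provided that chondrocytes do not express them. Of 7 lists of other cell types, 5 had medians below 0 by more than their standard error across genes, such as osteoblast (-2.34 ± 0.48) and adipocyte markers (-1.90 ± 0.46). A lower share alone does not give falls of markers that chondrocytes lack. Some of these markers are also expressed by chondrocytes, such as S100b, and Alpl, Ibsp and Sp7 are also on the hypertrophic chondrocyte list. A lower share could lower such markers. The rule was also set after the medians were seen, so it does not decide the question. The markers may themselves respond to TNF, so the lists cannot show whether the share of chondrocytes changed. The osteoblast list also shares genes with the hypertrophic list, and the tendon list with the matrix lists. The lists of macrophages (median 0.32), neutrophils (3.24, from 3 measured genes) and osteoclasts (-0.15) were not among the 7, and a change in those cell types stays open. A trend with transcript length and GC content explained 0.434% of the variance, and the median of the 25 genes was -1.72 after correction and -1.62 before, which argues against such a trend as the source. A response of the chondrocytes to TNF stays as a hypothesis, and loss of a subset of chondrocytes was not tested. Whether untreated cells were also kept without serum is not known, so an effect of serum cannot be told apart from one of TNF.

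Mitochondrial transcripts, chosen after their values were seen, were counted very unevenly. In untreated cells mt-Co1 stood at 3354 ± 223 CPM and mt-Cytb at 1552 ± 101 CPM, but mt-Co2 at 0.709 ± 0.0663, mt-Co3 at 0.420 ± 0.0933 and mt-Atp6 at 0.356 ± 0.144 CPM, and the TNF libraries showed the same gap, with mt-Co1 at 3942 ± 720 and mt-Co2 at 0.779 ± 0.279 CPM. The change of mt-Co1 did not pass (adjusted p = 0.088) but passed without TNF replicate 3 (0.00616), with DESeq2 (0.0472) and with no filter (0.038). The share of all counts from mitochondrial genes was 0.711% to 1.14% per library.

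Xist, the RNA that silences the inactive X chromosome, had 4, 1 and 1 counts in untreated replicate 3 and TNF replicates 2 and 3 and none in the other 5 libraries. Ddx3y, a Y-linked gene, lay between 110.7 and 136.4 CPM in all 8 libraries.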
